A study of Mus musculus with 3 samples.

How the data were processed

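Gene expression was measured in the CA1 field of the hippocampus of young male C57BL/6J mice, an inbred laboratory strain, on 3 short-oligonucleotide arrays of the Affymetrix type, as the probe-set names show. The labels put all 3 arrays in 1 group, contextual fear conditioning followed by RNA extraction 6 h after the last shock, and number them 1, 2 and 3. The labels do not say whether an array held RNA of 1 animal or of a pool, so the spread between arrays may hold animal, dissection and technical components together. No control group belongs to the samples used here, so no effect of conditioning was estimated and no comparison between groups was made.

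The deposited table gives 1 signal intensity per probe set and array, on a linear scale. Each array's mean signal after trimming 2% of probe sets at each end was 500.3, so the deposited arrays were already on a common scale. How the authors scaled them is not given. The program that made the signals, its version and its background correction are not given in the sources used here, and no detection calls were used. All 3 columns belong to the samples, and 0 columns of other samples were present. Probe sets were named through the platform's probe annotation, with symbols updated through Entrez identifiers to the GRCm38.p6 gene table. Of 12488 probe sets, 66 were array controls. Of the other 12422, 10833 had 1 gene symbol, 396 had several and were not named, and 1193 were unnamed in the annotation. The several-gene probe sets were not used for genes. The named probe sets covered 8251 genes. Genomic coordinates were not used here.

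For levels, the deposited signal is given as mean ± SD over the 3 arrays. For the spread between arrays, each array was rescaled to a common median over the measured probe sets, by factors of 0.991, 0.987 and 1.02, then floored at 47.5, the 25th percentile of all deposited values, and log2-transformed. A probe set was called measured when its mean over the arrays was above 175, the median of all deposited values. Control probe sets were left out. This left 6218 probe sets and 4876 named genes. A gene with several probe sets was represented by the brightest. The threshold stands in for a detection call, and a signal under it does not show that a transcript was absent.

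The spread was summarised as the SD of log2 signal, as the number of probe sets whose highest and lowest array were more than 2-fold apart, and as the number that set 1 array more than 2-fold apart from both others while those differed by under 0.5 on the log2 scale. Whether a probe set varied between arrays more than others at its level was tested with limma 3.58.1 in R 4.3.3. The variance of each probe set was set against a robust intensity-dependent prior (fitFDistRobustly, lower and upper tails winsorised at 0.05 and 0.1), and the upper-tail F probabilities were Benjamini-Hochberg adjusted with a threshold of 0.05.

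There were 28 gene lists, 13 of cell type markers and 15 of functions. The lists, the threshold, the floor, the variance test, the ranking of lists and the rule for named genes were fixed before the data were examined. Several genes belong to more than 1 list, among them Dcn, Cplx1, Calb2, Sst, Crem, Per1, Nfkbia and Camk2a. For each list and array, the shift was the median over measured genes of that array's log2 signal minus the mean of the other 2. Its percentile was taken among 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression, a number that was not part of that plan. Values outside the 2.5th to 97.5th percentile were counted. The SD of each list was treated likewise. Lists with fewer than 4 measured genes were not ranked. These percentiles describe the 3 arrays and are not tests across animals: members of a list can vary together for any reason, and the 3 shifts of a list are not independent. Each counted shift had the same sign as the list's mean shift. Variance-test p-values were also adjusted over each list alone.

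The genes named are the first 3 members of each list with a probe set, the 10 genes with the largest log2 range, taking first any past the variance test, and the 3 measured members that led each counted list. A gene named outside this rule was chosen after its values were seen. On simulated data with 200 of 6218 probe sets shifted on 1 array, in 5 rounds, the variance test called 0% of shifts of 1 log2 unit, 4% of 2, 53% of 3, 90% of 4 and 100% of 6. It made 10 false calls in all 5 rounds. In 10 further rounds on 4876 genes, with the arrays' deviations shuffled among genes of similar level, 5.0% of 720 list shifts were counted, and a shift of 0.5 on array 2 given to every member was counted in 72.5% of 120 lists. The number of arrays limits the precision of every value.

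The alternatives tried were no scaling, quantile normalization, cyclic loess, floors at the 10th and 40th percentiles, measured thresholds at the 25th and 75th percentiles or none, only probe sets with the plain suffix, the mean over a gene's probe sets, a prior without robust fitting, and each array left out. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.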

Results

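The data describe gene expression in hippocampal area CA1 of mice 6 h after contextual fear conditioning, a task in which an animal learns to associate a place with a foot shock. Mice spent 2 min in a new context before a shock of 1 s at 0.5 mA, and this cycle was given 3 times. They returned to the home cage 1 min after the last shock. Total RNA was measured on 3 replicate arrays of 12488 probe sets. The median signal was 176 on array 1, 177 on array 2 and 171 on array 3, and the highest signal was 74447, 65903 and 75624. Between 6 and 18 probe sets per pair of arrays carried identical values, so no array repeated another. Without unconditioned animals, the question the data can answer is which transcripts CA1 gave at this time and how far the 3 replicates differed. All values below are mean signal ± SD (n = 3 arrays) unless a single array is named, and a signal above 175, the median of all values, is called above threshold.

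Markers of CA1 pyramidal neurons were above threshold on every array. All 6 markers with a probe set passed, among them Wfs1, the wolframin gene, at 2522 ± 66.0, the transcription factor Pou3f1 at 579 ± 132, and the proteoglycan gene Dcn at 2839.6 ± 584. Of 7 general excitatory neuron markers 5 passed on all 3 arrays, with the transcription factor Neurod2 at 1249.5 ± 185, whereas Neurod1 gave 167 ± 26.8 and the kinase gene Camk2a gave 39.5 ± 4.90. Of 7 dentate granule markers 3 passed on all 3 arrays. The desmoplakin gene Dsp gave 225 ± 56.8 and the calcium-binding protein gene Calb1 gave 1563 ± 133, while Prox1 was under threshold at 28.4 ± 18.7. Interneuron markers passed for 9 of 11 genes, with the GABA-synthesising enzyme gene Gad1 at 4157 ± 550.4 and the somatostatin gene Sst at 10324 ± 1998, whereas Gad2 was under threshold at 118 ± 28.3. The shifts of these 4 lists on each array lay within the central 95% of random lists matched on mean expression, and 0 of their genes passed the limma variance test, adjusted over the list alone or over all probe sets. At an unadjusted p under 0.05, 1 gene did, Tbr1. The largest shifts were 0.47 for dentate granule markers on array 2 and 0.37 for excitatory neuron markers on array 3.

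Most astrocyte, oligodendrocyte and microglial markers were above threshold on all arrays, and vascular and blood markers were mostly under threshold. All 9 astrocyte markers passed on every array. The intermediate filament gene Gfap gave 1871 ± 394, the water channel gene Aqp4 956 ± 380.4 and the glutamate transporter gene Slc1a2 372 ± 96.7. Of 8 oligodendrocyte markers 6 passed, including the myelin genes Mbp at 8206 ± 882, Mobp at 12202 ± 582 and Mog at 540.0 ± 91.3. The other 3 probe sets of Mobp were highest on array 2 and lowest on array 3, at 1843, 4814 and 1496 for the brightest of them. Microglial markers passed for 8 of 10 genes, with the receptor gene Csf1r at 1647 ± 397 and the complement genes C1qa at 913 ± 291 and C1qb at 639 ± 143. Of 9 endothelial and pericyte markers 2 passed on all arrays. Cldn5 gave 384 ± 134, Pecam1 164 ± 49.7 and Cdh5 56.5 ± 45.8. Of 6 blood markers only the haemoglobin gene Hba-a1 passed, at 2253 ± 58.6, while Alas2 gave 67.1 ± 32.4 and Slc4a1 gave 109 ± 21.2. The astrocyte list was lower on array 3, with a median log2 shift of -0.16 and 5 of 9 genes below the other arrays, led by Aqp4 at -1.09, Slc1a2 at -0.51 and Apoe, the main brain apolipoprotein gene, at -0.35. That shift was at the 2.11th percentile of random lists, but it turned to 0.072 when all probe sets of a gene were averaged, was -0.12 and inside the random range without array 1, and was inside that range under 6 of 12 alternatives in all. The microglial list was shifted by -0.26 on array 1 and 0.31 on array 2, at the 1.5th and 98.45th percentiles. Cd68, Cx3cr1 and C1qb were lowest on array 1, with shifts of -0.51, -0.48 and -0.45, and C1qa was shifted by 0.71 on array 2, where 3 of 8 genes lay below the mean of the other arrays, among them Csf1r at -0.55. On that array the Gapdh ratio of 3' to 5' signal was 1.21, against 3.99 and 3.94 on arrays 1 and 3. The second probe set of Csf1r was highest on array 2, at 144, 244 and 168. The second probe set of C1qb was highest on array 1, at 232, 166 and 139. The microglial shifts fell inside the random range under 5 of 12 and 6 of 12 alternatives. Among these were -0.20 for array 1 without array 2 and 0.18 for array 2 without array 1, and without array 3 the shift of array 1 was -0.44. The oligodendrocyte shifts lay inside the random range, and the endothelial and blood lists had too few measured genes to be ranked. In these 5 lists, with each gene taken at its brightest probe set, 0 genes passed the limma variance test. This held adjusted over the list alone and over all probe sets. On that basis 1 gene, Aqp4, had an unadjusted p under 0.05. The brightest probe set of Mobp had a log2 range of 0.17, and the other 3 had 1.64, 2.14 and 1.06. Their limma p adjusted over all probe sets was 0.559, 0.515 and 0.955. The first 2 lie below the 0.899 of Aqp4, so their unadjusted p was also under 0.05. The count for Mobp thus depends on the probe set.

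Transthyretin (Ttr), the abundant secretory product of the choroid plexus, differed most between the arrays. Its signal was 1334, 4257 and 94.2 on arrays 1, 2 and 3, and it was the only one of 6218 measured probe sets past the variance test (limma, adjusted p = 0.049). The array 3 signal was under threshold. It lay above 55.6, the highest value on array 3 of 15 control probe sets for the Dap, Lys, Phe, Thr and Trpn transcripts of bacteria. It lay below 115, their highest value on any array, reached on array 2. The size of its range thus rests on a weak signal. The other measured choroid plexus and ependyma markers were also highest on array 2, without passing that test. The ciliary transcription factor gene Foxj1 gave 313, 508 and 166, the growth factor gene Igf2 1765, 2198 and 1582 and the klotho gene Kl 252, 366 and 351. Folr1, a folate receptor gene under threshold on average, gave 54.5, 196 and 39.9, and Aqp1, also under threshold on average, gave 160.4, 55.2 and 127, lowest on array 2. The median log2 shift of the 4 measured markers was 0.75 on array 2 and -0.74 on array 3, at the 99.75th and 0.07th percentiles of random lists, and the array 3 shift was -0.49 without array 2. With no threshold on the level the shifts were 0.37 and -0.27, the second inside the random range. Of the 4 genes, 1 passed the variance test adjusted over the list alone, and the same gene, Ttr, passed over all probe sets. The ratio of 3' to 5' Gapdh signal was 3.99, 1.21 and 3.94 on arrays 1, 2 and 3, and that of Actb was 2.57, 1.86 and 3.50. The limma adjusted p of Ttr was 0.066 after quantile normalization, 0.057 after cyclic loess, 0.051 without the robust prior, 0.053 at a higher threshold and 0.27 without array 2, in a range from 7.2e-05 to 0.93 over 13 alternatives. Its log2 range was 5.45 in the main setting, 5.50 after quantile normalization and 5.52 after cyclic loess, so these scalings did not shrink it. Without array 3 the range was 1.67.

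Markers of neighbouring tissue also differed between arrays. The 4 measured CA3 and CA2 markers all lay lower on array 1 than on the mean of the other arrays, with a median log2 shift of -0.70, lower than in any of 10000 random lists. The neuronal pentraxin gene Nptx1 gave 341, 868 and 766 on arrays 1, 2 and 3. Neuronatin (Nnat), an imprinted gene, gave 1042, 4862 and 885, which set array 2 apart. Bok gave 657, 812 and 896 and Prss23 was under threshold at 132 ± 30.8. On array 2, where the Gapdh ratio of 3' to 5' signal was 1.21 against 3.99 and 3.94, the list was shifted by 0.39, at the 98.07th percentile. Over the list alone, Nnat and Nptx1 passed the variance test, with adjusted p of 0.0019 and 0.042 in limma, and 0 of the 4 passed over all probe sets. The array 1 shift was -0.40 without array 2 and with no threshold, still outside the random range. The array 2 shift was inside it at 0.011 without array 1, 0.03 at the lower threshold and 0.05 with none, and was 0.82 without array 3. Meningeal and fibroblast markers were higher on array 1, with a median shift of 0.49 at the 99.99th percentile and the highest signal there for 6 of 8 genes. The prostaglandin D synthase gene Ptgds gave 8808, 4634 and 4726, the matrix Gla protein gene Mgp 329.7, 145 and 250.2, and the collagen gene Col1a1 365, 194 and 306. The other probe sets of Ptgds gave 7359, 5327.5 and 5170, and 5916, 5559 and 5059, also highest on array 1 but closer together. Col1a2 gave 2213 ± 349 and Col3a1 gave 114 ± 25.9. Igfbp2, at 386, 1002 and 258, and Slc6a13, at 218, 455 and 402, went the other way, and 0 of 8 passed the limma variance test adjusted over the list alone or over all probe sets, with 2, Igfbp2 and Ptgds, at an unadjusted p under 0.05. Thalamic markers were more variable than random lists, with a median SD of 0.47 at the 99.25th percentile, led by Cplx1, Tcf7l2 and Rora. Tcf7l2 gave 282, 664 and 518 and Rora 224, 227 and 118, while Prkcd gave 511 ± 74.2 and Lef1 489 ± 37.7. That median SD was inside the random range over probe sets with the plain suffix, at 0.24, without array 2, at 0.24, and without array 3, at 0.19. Cplx1, which also belongs to the vesicle release list, was the 1 thalamic member past the variance test adjusted over the list alone, and 0 passed over all probe sets.

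Genes of vesicle release and ionotropic glutamate receptors shifted together, up on array 2 and down on array 3. The 11 measured vesicle release genes had median log2 shifts of 0.43 on array 2 and -0.71 on array 3, the first at the 99.92nd percentile of random lists and the second lower than in any of them. On array 3, 8 of the 11 lay below the mean of the other arrays. Complexin 1 (Cplx1), a regulator of vesicle fusion, gave 1417, 3458 and 1124 on arrays 1, 2 and 3. The vesicle proteins synaptotagmin 1 (Syt1) and synaptophysin (Syp) gave 1187, 1991 and 797, and 840.2, 1631 and 661, and the small GTPase gene Rab3a gave 564, 442 and 184. Other members did not share this order. Snap25, which encodes a fusion protein of the presynaptic membrane, gave 19781 ± 943 and Stx1a 958 ± 118, and Dnm1, the dynamin 1 gene, was highest on array 3, at 23447, 22794 and 34836. The 6 measured glutamate receptor genes were shifted by 0.53 on array 2 and -0.61 on array 3, at the 99.51st and 0.01st percentiles. The AMPA receptor gene Gria1 gave 7192, 8130.1 and 3565, and its second probe set gave 898, 1286 and 586, in the same order. Gria3 gave 497, 363 and 176, the NMDA receptor gene Grin2b 101, 400.2 and 158, and the kainate receptor gene Grik5 416, 1550.4 and 493, whereas the brightest probe set of Gria2 gave 11446 ± 708. Its 2 other probe sets gave 1225, 962 and 1346, and 801, 1195 and 839, in different orders. Both lists were more variable than random lists, with median SDs of 0.43 and 0.68, but not without array 2, at 0.21 and 0.34, or without array 3, at 0.23 and 0.32. In the vesicle list 0 genes and in the receptor list 1 gene, Grik5, passed the variance test adjusted over the list alone, and 0 genes of either list passed over all probe sets in limma. At an unadjusted p under 0.05 there were 4 in the vesicle list, Syt1, Cplx1, Rab3a and Syp, and 3 in the receptor list, Gria1, Gria3 and Grik5. The ratio of 3' to 5' signal was 3.99, 1.21 and 3.94 for Gapdh on arrays 1, 2 and 3, and 2.57, 1.86 and 3.50 for Actb, whose 3' signal was 41349, 31982 and 19166. Choroid plexus and ependyma markers were also shifted by 0.75 on array 2 and -0.74 on array 3. Without array 3 the receptor shift on array 2 was 0.17, inside the random range, and without array 1 it was 1.06, which with 2 arrays left also fixes the shift on array 3, at -1.06. The vesicle shifts stayed outside the random range, at 0.64 on array 2 without array 1 and -0.29 on array 3 without array 2, and on array 3 were -0.35, -0.42 and -0.37 at the lower threshold, the higher and none. The receptor shift on array 2 was 0.86 at the lower threshold.

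**Figure D1:**
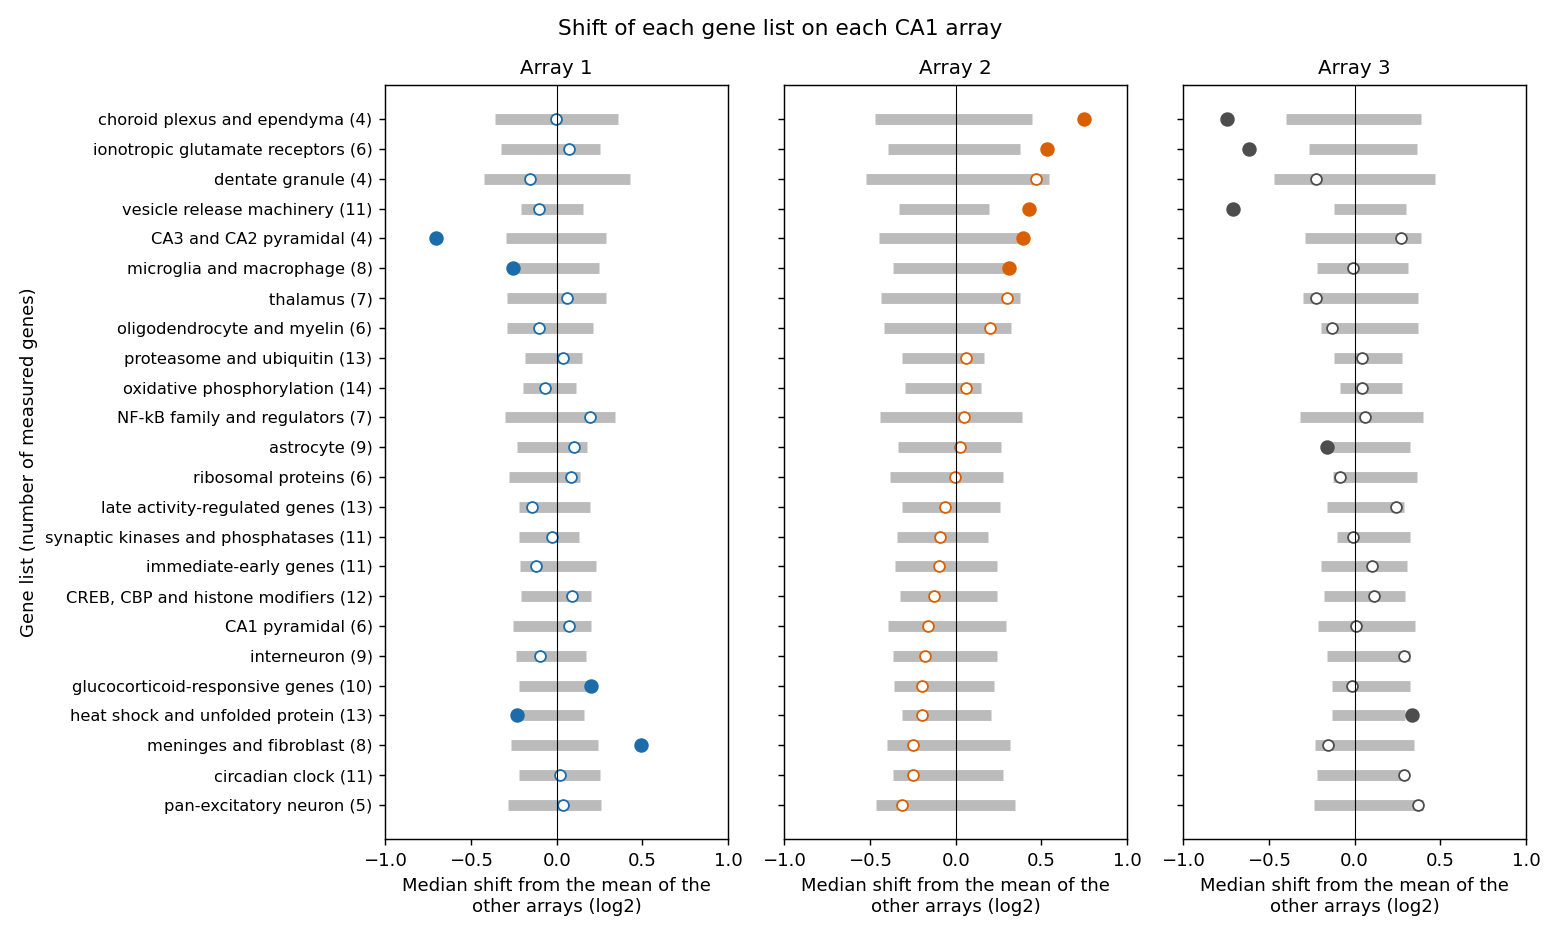
Median log2 shift of each gene list (vertical axis, with the number of measured genes) on array 1, 2 and 3, each against the mean of the other arrays. Grey bars span the central 95% of 10000 random lists matched on mean expression, filled points lie outside them and open points inside; vesicle release genes sit at 0.43 on array 2 and -0.71 on array 3.

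**Figure D2:**
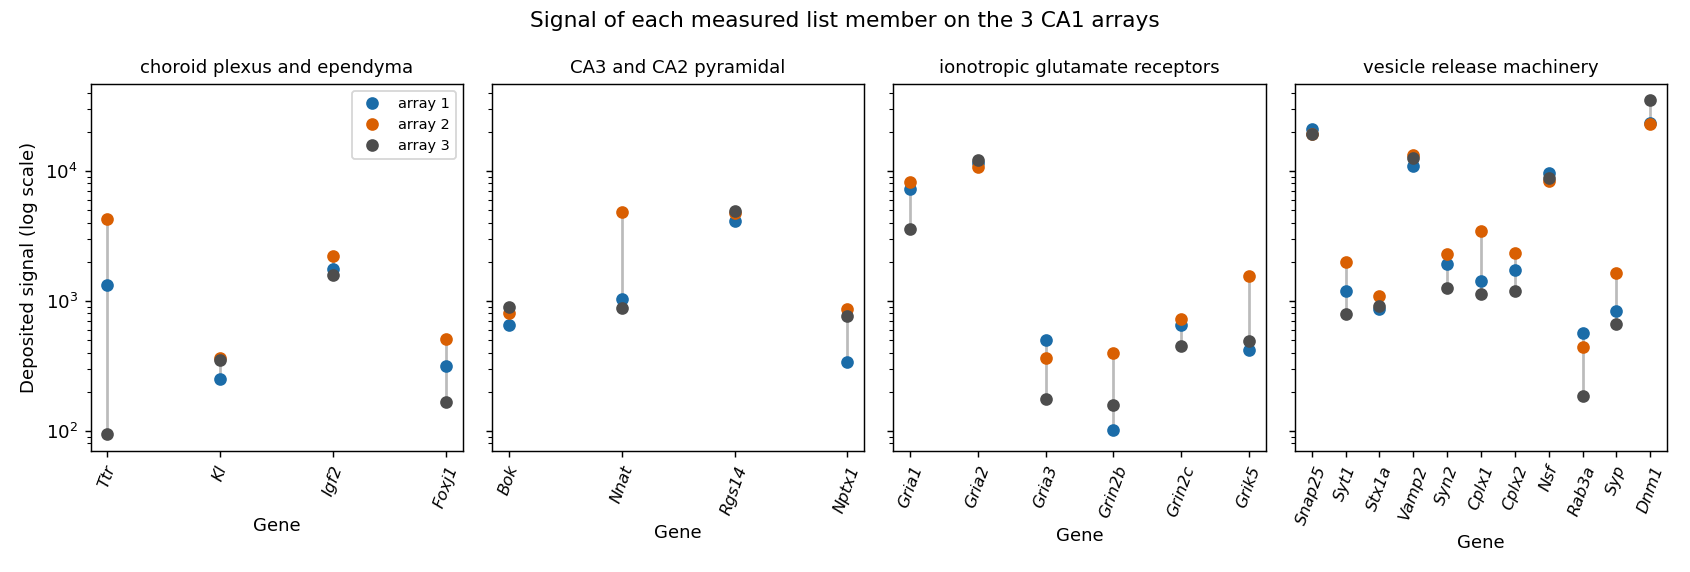
Deposited signal (log axis) on arrays 1, 2 and 3 for each measured gene of 4 lists, with a grey line from the lowest to the highest array. Ttr spans 94.2 to 4257 and is highest on array 2, while the brightest probe sets of Snap25, Nsf and Gria2 lie close together on the 3 arrays.

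Lists of genes that respond to neuronal activity were not set apart on any array 6 h after training. Of 15 immediate-early genes with a probe set 10 were above threshold on all arrays. The transcription factor genes Fos and Fosb gave 227 ± 40.8 and 501 ± 16.5, and Fosl2 gave 137 ± 113. Of 15 late activity-regulated genes 12 passed. Bdnf, the neurotrophin gene, gave 2465 ± 419, the neuronal pentraxin gene Nptx2 314 ± 4.90, and Inhba, which passed on 1 array, 163 ± 33.5. Among NF-kB genes, a transcription factor family with roles in synaptic signalling, 5 of 13 passed on all arrays. Rela gave 1162 ± 42.9, Relb gave 189 ± 92.9, and Rel, which encodes c-Rel, gave 41.0 ± 38.9, under threshold on each array. Of 14 genes for CREB-related factors and histone or DNA modifying enzymes 10 passed on all arrays, with Atf2 at 2230.5 ± 306. Crem, at 179 ± 42.6, passed on 1 array and Creb1, at 97.4 ± 36.0, on 0. Shifts and spreads of these 4 lists lay inside the central 95% of random lists, with median SDs from 0.19 for NF-kB genes to 0.34 for the CREB and histone modifier genes. In each of the 4 lists 0 genes passed the limma variance test, adjusted over the list alone or over all probe sets, and at an unadjusted p under 0.05 there were 2, Jund and Crebbp. Without control animals, none of these levels can be read as induced or unchanged by training.

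Inhibitory receptor subunits and synaptic kinases were measured in part. Of 6 GABA-A subunit genes 2 passed on all arrays, Gabra2 at 696 ± 179.8 and Gabrb1 at 6308 ± 773, while Gabra3 gave 23.4 ± 14.3, and this list had too few measured genes to be ranked. Of 13 kinase and phosphatase genes 11 passed. Camk2b gave 8840.2 ± 279, whereas Camk4 gave 114 ± 15.8. The shifts of the kinase list lay between -0.09 and -0.01, inside the random range on each array, and 0 of its genes reached an unadjusted p under 0.05 in limma, so 0 passed adjusted over the list alone or over all probe sets.

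Heat shock and unfolded protein genes were higher on array 3, with a median log2 shift of 0.34 at the 98.97th percentile and 12 of 13 genes above the mean of the other arrays, and lower on array 1, with a shift of -0.23 at the 1.78th percentile. The inducible chaperone gene Hspa1a gave 684, 446 and 871 on arrays 1, 2 and 3, the co-chaperone gene Dnajb1 578, 578 and 775 and the endoplasmic reticulum gene Pdia4 208, 238 and 344. On array 1 the mitochondrial chaperone gene Hspd1 was shifted by -0.48 and Ddit3 by -0.66, but the second probe set of Hspd1 was highest on array 1, at 268, 135 and 203. Hspa1b gave 365 ± 42.1 and Hspa5 1916 ± 287. On array 3, where the Actb ratio of 3' to 5' signal was 3.50 against 2.57 and 1.86, choroid plexus and astrocyte markers were shifted by -0.74 and -0.16. The astrocyte shift turned to 0.072 when a gene's probe sets were averaged. Pooled, the 14 measured excitatory neuron and interneuron markers were shifted up on array 3 by 0.33, at the 99.43rd percentile. Neither of those lists lay outside the random range alone, and the pool was formed after list values had been seen. It leaves out the CA1, the CA3 and CA2, and the dentate markers, at 0.0076, 0.27 and -0.22, each inside the random range. Glucocorticoid-responsive genes were higher on array 1 by 0.20, at the 98.53rd percentile, with 8 of 10 genes above the mean of the other arrays. On the same array meningeal and fibroblast markers were shifted by 0.49, CA3 and CA2 markers by -0.70 and microglial markers by -0.26. Cdkn1a gave 299, 99.5 and 165, the kinase gene Sgk1 1858, 1081 and 1192 and Klf9 5468, 4022 and 3665, with 555, 505 and 560 on its second probe set, while Fkbp5, a co-chaperone of the glucocorticoid receptor, gave 1064 ± 154 and Tsc22d3 82.3 ± 47.9. In both lists 0 genes passed the limma variance test, adjusted over the list alone or over all probe sets, and 0 had an unadjusted p under 0.05. The glucocorticoid shift fell inside the random range under 5 of 12 alternatives, among them 0.19 after quantile normalization and 0.25 without array 3. The heat shock shifts did so under 4 of 12 on array 1, among them -0.19 without array 3, and under 1 of 12 on array 3, with 0.29 without array 1. Without array 2 the array 1 shift was -0.39. Clock genes passed for 11 of 12 genes, with the period genes Per1 at 447 ± 27.8 and Per3 at 215 ± 34.5, while Per2, at 163 ± 21.3, passed on 1 array. Their shifts lay inside the random range, with 0 genes past the limma variance test and 0 at an unadjusted p under 0.05.

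The 6 measured ribosomal protein genes varied least of the 24 ranked lists, with a median SD of 0.097 on the log2 scale, at the 1.73rd percentile of random lists. Rpl7 gave 6652 ± 461, Rpl8 9454 ± 511, Rpl19 14821 ± 1297 and Rps7 9423 ± 513. Under 7 of 13 alternatives that SD fell inside the random range, among them 0.11 with no scaling, 0.13 after quantile normalization, 0.15 after cyclic loess, 0.081 without array 2 and 0.12 without array 3, so the result depends on the scaling, and without array 1 it was 0.047. Of 16 oxidative phosphorylation genes 14 passed on all arrays, with the ATP synthase genes Atp5a1 at 10481 ± 369 and Atp5c1 at 6620.2 ± 637 and the cytochrome oxidase gene Cox4i1 at 479 ± 85.1. All 13 proteasome and ubiquitin genes passed, with Psma1 at 451 ± 77.2, Psma2 at 2970.1 ± 170.0 and Psma3 at 5519 ± 906. Neither list was shifted on any array beyond the random range. In the 3 lists 0 genes passed the limma variance test, adjusted over the list alone or over all probe sets, and 1 gene, Uqcrc1, had an unadjusted p under 0.05. Xist, the X-inactivation RNA of female cells, gave 16.2 ± 14.5, and the Y-linked genes Eif2s3y and Kdm5d gave 189 ± 51.8 and 41.7 ± 30.6. The animals were labelled male.

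Over all measured probe sets the median SD was 0.25 on the log2 scale, with quartiles of 0.16 and 0.39. The arrays lay within 1.5-fold of one another for 3873 probe sets (62.3%) and more than 2-fold apart for 755 (12.1%). Besides Ttr, the genes with the largest ranges were B4galt2, Nxph1, Os9, Doc2b, Tcf7l1, Hira, Commd5, Gnaz and Klhl7. Each has an array with a signal below 115, the highest value of the same 15 control probe sets on any array, so the size and order of these ranges are not given. None of them passed the variance test, with limma's adjusted p at or above 0.515. At an unadjusted p under 0.05, 324 probe sets were more variable than the trend, where 310.9 were expected by chance. The trend and prior were fitted to these same variances, so a count near that number is built in. It does not show that an excess of variable probe sets was absent. Array 2 set itself apart most often, with 114 probe sets higher and 65 lower than on both other arrays. The corresponding counts were 17 and 25 on array 1, and 11 and 53 on array 3. Across measured probe sets, Pearson's r was 0.955 for arrays 1 and 3, 0.929 for arrays 1 and 2, and 0.920 for arrays 2 and 3, and Spearman's rho was 0.944, 0.913 and 0.903. These are correlations across genes, which are not independent replicates. Without array 2 the median SD was 0.17 and 218 probe sets were more than 2-fold apart. Leaving out array 1 or array 3 gave 486 and 411. The variance test called 0 probe sets without array 2 and 50 without array 3.

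Control probe sets also separated array 2, and the Actb signals set array 3 apart. The 3' to 5' signal ratio of Gapdh, a measure of how far labelled RNA extends toward the 5' end, was 3.99 on array 1, 1.21 on array 2 and 3.94 on array 3. For Actb it was 2.57, 1.86 and 3.50. The 5' Gapdh signal was 28001 on array 2, against 9368 and 9670.0. The Actb signals were lowest on array 3, with 27491, 23249 and 9489.5 on arrays 1, 2 and 3 for the middle probe set. The 5' probe set of Actb gave 16086.5, 17218 and 5472. All 9 probe sets for the bacterial and phage hybridization transcripts were lowest on array 2, at 0.55 to 0.74 of the mean of the other arrays. Of 72 list shifts, 15 lay outside the central 95% of random lists, where 3.6 would be expected for lists without shared variation. Of 24 list spreads 7 lay outside, 6 above and 1 below, where 1.2 would be expected. With 2 arrays left, the 2 shifts of a list mirror each other, so lists are counted once: 4 of 24 without array 1, 11 of 24 without array 2 and 5 of 24 without array 3. Without array 2 or array 3, 2 of 24 spreads were counted.

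**Figure D3:**
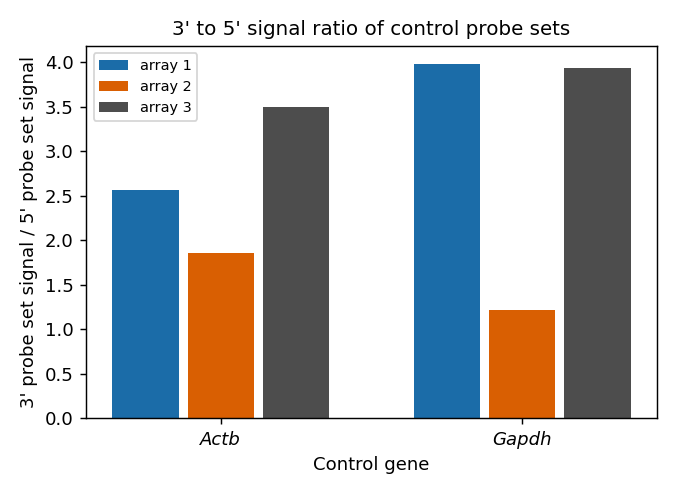
Ratio of 3' to 5' probe set signal (vertical axis, no unit) for the control genes Actb and Gapdh, with 1 bar per array. Array 2 has the lowest ratio for both genes, 1.86 for Actb and 1.21 for Gapdh.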

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

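The direction of every counted list shift was kept under the alternatives run, with 1 exception: the astrocyte shift on array 3, -0.16, became 0.072 when a gene's probe sets were averaged. All alternatives were chosen before the data were examined. Scaling and floor moved no count by more than 1.5 times, except that 0 probe sets passed the limma variance test under quantile normalization and cyclic loess. The prior without robust fitting also gave 0, where the main setting gave 1, with 324 at an unadjusted p under 0.05. At the 25th percentile, the median SD was 0.32, 2425 probe sets were over 2-fold apart, 6 passed the variance test and 1105 were specific to an array (300, 470.0 and 335 on arrays 1, 2 and 3). At the 75th percentile the counts were 205, 0 and 84 (9, 61 and 14), and 3 list spreads were counted. With all probe sets they were 2450.0, 1375 and 1137 (308, 479 and 350.0), with a mean correlation of 0.955; there the variance test is void, since probe sets at the floor have no variance. With plain-suffix probe sets only, 8 of 66 list shifts and 3 of 22 list spreads were counted. Leaving out 1 array gave a median SD of 0.165 to 0.242, 218 to 486 probe sets over 2-fold apart, 0 to 50 past the variance test, a mean correlation of 0.921 to 0.956, 8 to 22 list shifts of 48 (24 lists, each on both arrays left, with opposite signs), and 2 to 5 list spreads of 24. The low values of SD and 2-fold count and the high correlation came without array 2, and the 50 calls came without array 3. List genes above threshold on all arrays numbered 193 of 278, and 196 to 199 with an array left out; this count has no value without a threshold. The adjusted p of Ttr lay between 7.2e-05, at the 25th percentile, and 0.93, in the void fit of all probe sets. Among the log2 ranges of named genes, 112 of 1058 values moved by more than 1 SD. The 841 list shifts under alternatives cover all ranked lists, but only the 15 shifts counted in the main setting could be lost. Among the values of those 15, 32 were no longer counted, 1 of them reversed. Per counted shift, the loss was 0 to 6 of 10 to 12 alternatives. Among the values of the other shifts, 32 were newly counted. The cause of these changes was not tested. Without detection calls, dim probe sets cannot be told from background. No paired analysis was possible because there was a single group.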

Other observations

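Several transcripts known to be abundant in brain or in every cell gave mean signals below 115. That was the highest value of the 15 control probe sets for the Dap, Lys, Phe, Thr and Trpn transcripts of bacteria, reached on array 2. The median of those control values was 14.7, which the transcripts named here exceeded. Camk2a, the calcium/calmodulin-dependent kinase of excitatory neurons, gave 39.5 ± 4.90 on the brighter of its 2 probe sets. The ribosomal protein genes Rpl32 and Rps15 gave 59.1 ± 30.5 and 56.5 ± 29.3, the myelin enzyme gene Cnp gave 62.3 ± 30.6, and the glucocorticoid receptor gene Nr3c1 gave 44.6 ± 9.95. These members were singled out after their values were seen. A low signal of a probe set here does not show that its transcript was scarce. The control probe set at the 3' end of 18S ribosomal RNA gave 2185, 1053 and 416 on arrays 1, 2 and 3.

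In what follows, the scaling tests of the choroid plexus markers and the neuron share test were chosen after the result was seen. The other tests were set down before their outcome was seen. They use the genes whose list shifts had defined each pattern, so they are not independent of it. The scaling test had first been set on the log2 range of Ttr alone, at 5.50 to 5.52 under the other scalings. It was replaced because the array 3 signal of Ttr, at 94.2, is weak and under threshold. That signal is still above 55.6, the highest value of the Dap, Lys, Phe, Thr and Trpn controls on that array. The neuron share test had first been set on the astrocyte markers, whose array 3 shift was -0.16 and turned to 0.072 under 1 alternative. It was then moved to excitatory neuron and interneuron markers. Next it required each neuron list to pass on its own, which none did and which was dropped, and last it took in all 5 neuron lists, each time with earlier values known, so its outcome carries less weight. No biological explanation was tested, because the design names 1 group only.

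Choroid plexus and ependyma markers were high on array 2, and the other scalings did not remove this. Under no scaling, quantile normalization and cyclic loess, the median of array 2 minus array 1 over 4 markers was 0.60 to 0.63. That was above the random range under each. No scaling differs from the main setting by a constant factor per array and could not change the rank. Random lists matched on mean expression share a scaling error that depends on level. These values show a difference from genes of like level under every scaling, but do not decide on scaling as a cause. The markers were low on array 3, with a shift of -0.76 to -0.79 under these scalings. Only 2 of the 4 were above threshold on that array, so scaling stays open there too. The limma adjusted p of Ttr was 0.066 and 0.057 after quantile normalization and cyclic loess, in a range from 7.2e-05 to 0.93 over 13 alternatives. Its log2 range was 5.50 and 5.52 under those 2 scalings, against 5.45 in the main setting, so the lost calls do not reflect a smaller difference. Choroid plexus tissue taken along in unequal amounts is a candidate explanation, which predicted that the 3 measured markers other than Ttr would be highest on array 2 and lowest on array 3, and 2 of the 3 were. Kl was lowest on array 1. These markers had helped to define the pattern, so the count is not independent support, and 3 markers are too few to decide. Of 3 markers under threshold on average, Folr1 was in the predicted order at 54.5, 196 and 39.9, Aqp1 was lowest on array 2 at 160.4, 55.2 and 127, and Cldn2 gave 35.2 ± 2.45.

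Vesicle release and glutamate receptor genes were higher on array 2 than on array 3 by a median of 0.92 on the log2 scale over 17 genes. Quantile normalization and cyclic loess did not remove it: the difference was 0.97 and 1.03, above the random range under both. The genes came from lists picked for being high on array 2 and low on array 3. Random lists matched on mean expression also share a scaling error that depends on level. This test could thus hardly come out otherwise and does not decide on intensity-dependent scaling. A lower share of neurons on array 3 would lower neuron markers there. The 14 measured excitatory neuron and interneuron markers were shifted up there by 0.33. That was at the 99.43rd percentile of random lists. Under the 3 other scalings the shift was smaller, at 0.26 to 0.28, and its percentile was 99.43 to 99.72. No scaling could not change that rank. Over 28 markers of 5 neuron lists the median array 3 shift was 0.18, and 0.077 under cyclic loess. No random lists were drawn for these 28 markers. For the 5 lists taken singly, random lists had medians of 0.034 to 0.11 on array 3 in the main setting. A shift above 0 is thus not particular to neuron markers. The median of array 2 minus array 3 over the 28 markers was -0.18, short of 0.92 by 1.11. The SD over genes of 0.68 is a spread between markers, not an error of that median. The array 3 shifts of CA1 and dentate markers alone were 0.0076 and -0.22. As a set these markers gave no sign of a lower neuron share, but the test was rewritten with values known, so no verdict is drawn from it. Unequal coverage along transcripts, seen in the Gapdh and Actb ratios, may contribute. The log2 difference of array 2 minus array 3 was compared between probe sets of the same gene. Its range within a gene had a median of 0.65 over the 4 list genes with several measured probe sets. That was at the 62.01st percentile of random sets, whose median was 0.55. Those sets came from the same arrays and share any general difference in coverage, so the test could not detect it. The 4 genes are also too few to decide.

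CA3 and CA2 markers were shifted down on array 1. The median shift was between -0.68 and -0.71 under the 3 other scalings, so these did not remove it. No scaling differs from the main setting by a constant factor per array and could not change the rank. Random lists matched on mean expression share a scaling error that depends on level. The test therefore does not decide on scaling as a cause. CA3 or CA2 tissue in unequal amounts is a candidate explanation: it predicted that all 4 measured markers would be lowest on array 1, and 3 of 4 were. Nnat was lowest on array 3, at 1042, 4862 and 885. The same markers had defined the pattern, so the count is not independent support, and 4 markers are too few to decide.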
